A study of Mus musculus with 26 samples.

How the data were processed

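The series holds 26 libraries of mouse poly(A) RNA in 9 groups. MC38/gp100 is a mouse colon adenocarcinoma line that carries the melanoma antigen gp100, and pmel-1 T cells come from transgenic mice whose T cell receptor recognises that antigen. The MC38 libraries cover a wild-type line and a line with Mtap knocked out (KO). Mtap encodes methylthioadenosine phosphorylase, the enzyme that clears methylthioadenosine (MTA). Cells received DMSO, GSK3326595, an inhibitor of the arginine methyltransferase PRMT5, or MRTX1719, an inhibitor that binds PRMT5 together with MTA. The labels' treatment field gives GSK3326595 with another last digit in replicates 2 and 3, while the titles do not, and the libraries were taken as treated with 1 compound. Each inhibitor was given at 0.5 uM, for 5 days to MC38 cells and for 3 days to T cells, which were kept in IL-2. Per the labels' protocols, RNA was isolated with Trizol and a column kit, made into directional poly(A) libraries and sequenced on a NovaSeq X plus. Each group has 3 libraries, except wild-type MC38 cells with MRTX1719, which have 2 (replicates 1 and 3).

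The authors deposited raw counts per gene and a second table of normalized signal, separately for MC38 cells and for T cells. Per the submitters' processing notes, TopHat2 2.0.10, Bowtie2 2.1.0 and DESeq 1.18.0 were used with the GRCm39 (mm39) build. The counting program, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may be shared or split. The deposited raw counts are whole numbers with no normalization. The authors' normalized signal was tested against them and equals the raw counts divided by 1 size factor per library. Matching by these values within 1e-06 tied 15629 of 15629 entries of the MC38 table and 15287 of 15300 of the T cell table to a single gene identifier, which then took the authors' symbol. Other identifiers were named from the supplied table of gene names. Where both sources named a gene, 14727 of 15190 names were the same in MC38 cells and 14360 of 14844 in T cells. No name was found for 4144 and 4140 identifiers. Coordinates are not given, because the annotation used here for neighbouring genes and transcript sequences is of the older GRCm38 build.

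Library totals ran from 19302768 to 27786226 counts in MC38 cells and from 13813406 to 20772699 in T cells. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene of 1.40 to 2.83 in MC38 cells and 1.96 to 3.74 in T cells, and no pair held identical values. The labels number the replicates and do not say whether they came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. The common biological coefficient of variation was 0.0198 in MC38 cells and 0.0372 in T cells.

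The tests used R 4.3.3. Raw counts of each table were fitted with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood F test), with all groups of a table in a single fit and no covariates. The filter left 14835 genes in MC38 cells and 13753 in T cells. Every gene-level adjusted p in the text is from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Fold changes are on the log2 scale, and the number after ± is then a standard error. Levels are CPM, counts scaled to a fixed library total, on TMM-scaled library sizes, as mean ± SD over the libraries of a group. There were 12 comparisons: KO against wild-type under DMSO, each inhibitor against DMSO in both MC38 lines and in T cells, the difference of each inhibitor's effect between the MC38 lines, and MRTX1719 against GSK3326595 in each kind of cell. MC38 cells and T cells were normalized and fitted separately, so differences between them were not tested.

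Gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered interferon-stimulated genes, MHC class I presentation, cytosolic nucleic acid sensing, p53 targets, MDM2/MDM4 and p53, mitosis, DNA replication, homologous recombination and Fanconi genes, the PRMT5 complex and Sm proteins, arginine methyltransferases, methionine metabolism, polyamine metabolism, ATF4 targets, the unfolded protein response, cholesterol synthesis, glycolysis, ribosome biogenesis, apoptosis regulators, and polyadenylated and replication-dependent histones. For MC38 cells they added checkpoint ligands, chemokines and cytokines, NKG2D ligands and death receptors, mesenchymal, epithelial and melanosome genes, and markers of leukocytes, fibroblasts and endothelium. For T cells they added effector, exhaustion, memory, trafficking, T cell receptor and gamma chain cytokine genes, and markers of B cells, CD4 T cells, myeloid cells and NK cells. Immediate early and heat shock genes and nuclear retained RNAs served as signs of handling and RNA quality. Lists share some members. In all, 30 lists were tested in MC38 cells and 32 in T cells, each with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over the lists of a comparison, and again with an estimated correlation. Markers of red cells and platelets and messenger RNAs encoded by mitochondrial DNA had no tested member and gave no result.

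Named genes were Mtap, Prmt5 and Pmel in every group, the 8 genes that rose most and the 8 that fell most in a comparison, and up to 4 members of a list with the largest changes, or 2 where none passed. Top genes needed a mean of at least 1 CPM in the higher group and, outside interactions, no overlap between the libraries compared. Predicted gene models, pseudogenes and mitochondrial genes were left out. Among the list members so named, those given as examples in the text were mostly picked after their values were seen, as members whose call held in every alternative; where it did not, the text says so. Genes followed into a comparison where the rule did not name them are given with their values. Against a group with 0 counts the fold is a lower bound from a floor of 3 counts over the group, and against a group with 1 to 3 counts it is a ratio with an exact 95% counting interval. Both cover counting error only.

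The alternatives were median-of-ratios scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-trend on log2 of the authors' normalized signal plus 1, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and the fry test. The test was tried on simulated data made from the real means and library sizes, with 50 genes changed by each of several folds. For GSK3326595 in wild-type MC38 cells it found 35, 47, 49 and 50 of the 50 genes changed 1.25, 1.5, 2 and 4-fold, and 10 unchanged genes (5.2% of its calls). For MRTX1719 in wild-type MC38 cells it found 36, 44, 48 and 50, with 10 unchanged genes (5.3%), and for GSK3326595 in T cells 27, 37, 46 and 50, with 15 (8.6%).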

Results

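RNA was measured by poly(A) RNA sequencing in 17 libraries of MC38/gp100 mouse colon adenocarcinoma cells and in 9 libraries of pmel-1 T cells. The MC38 cells were a wild-type and an Mtap knockout (KO) line, each with DMSO, GSK3326595 or MRTX1719, in 3 libraries per group except wild-type with MRTX1719, which had 2. The T cells had the same 3 treatments in 3 libraries each. Total counts were 19302768 to 27786226 per MC38 library and 13813406 to 20772699 per T cell library. The series is about MTA-cooperative inhibition of PRMT5, and the design sets an inhibitor that works together with MTA beside another PRMT5 inhibitor, in tumour cells with and without an Mtap knockout and in T cells.

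Mtap RNA was lower in the KO line but far from absent. It stood at 393 ± 4.61 CPM in wild-type cells under DMSO (SD, n = 3) and at 271 ± 6.31 CPM in KO cells (n = 3), a log2 fold change of -0.53 ± 0.022 (SE; adjusted p = 1.65e-49, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With GSK3326595 it was 419 ± 2.44 CPM in wild-type and 246 ± 8.51 CPM in KO cells, and with MRTX1719 it was 399 ± 0.467 CPM (n = 2) and 205 ± 1.72 CPM. Every KO library thus lay below every wild-type library, but whole-gene counts include RNA that an edit may leave in place, so they check the labels only in part. In T cells Mtap was at 79.3 ± 3.91, 79.4 ± 0.474 and 85.0 ± 2.03 CPM with DMSO, GSK3326595 and MRTX1719. Prmt5, the target of both inhibitors, was at 145 CPM in wild-type and 97.5 CPM in KO cells under DMSO. Its log2 fold changes with the inhibitors ran from -0.22 in T cells with GSK3326595 to 0.17 in KO cells with MRTX1719. Pmel, the mouse gene for gp100, was near the floor, at 1.69 CPM in wild-type and 2.06 CPM in KO cells under DMSO. Its log2 fold changes in KO cells were -0.81 with GSK3326595 and -1.19 with MRTX1719 (adjusted p = 0.000718 and 2.42e-06). Whether these counts hold RNA of the gp100 that the line carries was not tested, so they do not show a change of that antigen.

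**Figure D1:**
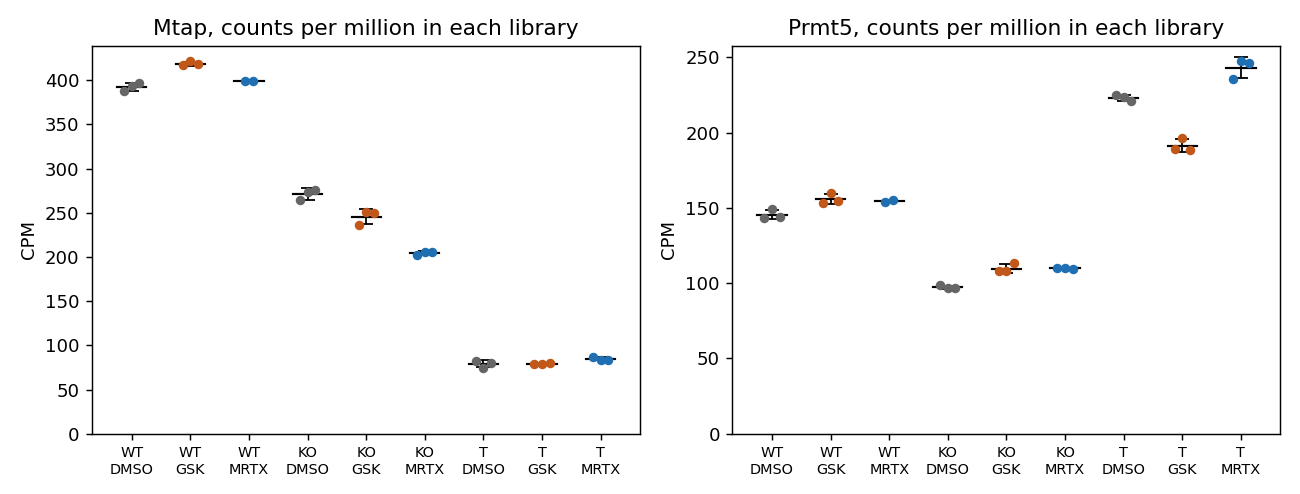
Mtap and Prmt5 levels in CPM for each library (points) in the 9 groups, with the group mean (line) and SD. Mtap lay at 393 CPM in wild-type and 271 CPM in KO cells under DMSO and at 79.3 CPM in T cells, so the KO libraries keep most of the RNA.

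In wild-type MC38 cells 6102 genes changed with GSK3326595 and 1117 with MRTX1719. The latter count, from 2 treated libraries, was 433 without MRTX1719 replicate 1 and 510 without replicate 3, the lone library left being assumed to vary like the other groups. In KO cells 7830 changed with GSK3326595 and 10464 with MRTX1719. T cells had 7260 and 5140 changed genes. Most changes were small, since 344, 18, 546 and 1779 genes moved at least 2-fold in the same 4 MC38 comparisons, and 815 and 259 in T cells. KO and wild-type cells under DMSO differed at 10854 genes, 2223 of them at least 2-fold.

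**Figure D2:**
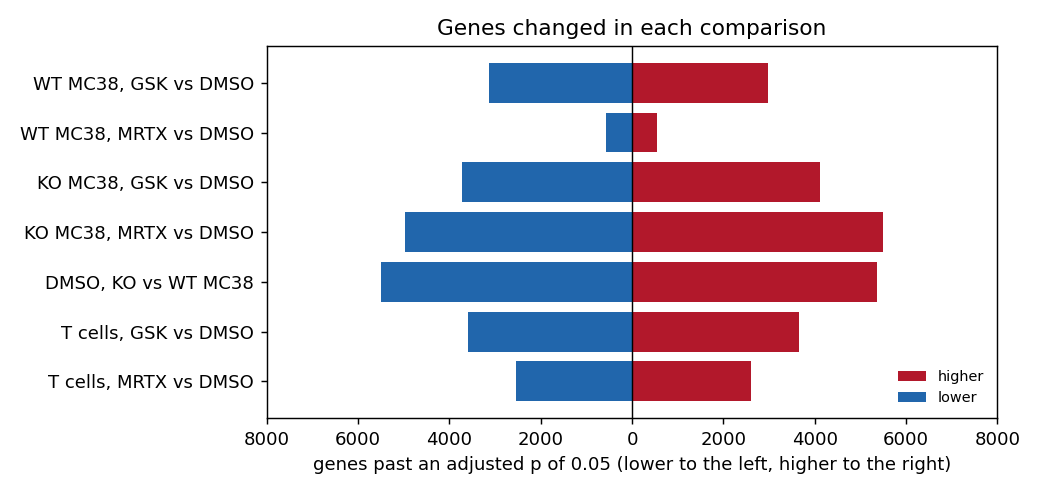
Number of genes with adjusted p below 0.05 in 7 comparisons. Genes higher in the group named first (inhibitor or KO) are to the right, and genes lower in it to the left. MRTX1719 changed 1117 genes in wild-type and 10464 in KO MC38 cells, and the KO line differed from the wild-type line at 10854 genes.

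The first comparison asked how the Mtap KO line differed from the wild-type line with no inhibitor. The KO line carried more RNA for cholesterol synthesis and mitosis, and less for immediate early and interferon-stimulated genes. Of 10854 changed genes, 5367 were higher and 5487 lower in KO cells. Col12a1, which encodes collagen XII, went from 3.18 ± 0.356 to 105 ± 3.27 CPM (SD, n = 3 each), a log2 fold change of 5.05 ± 0.062 (adjusted p = 9.59e-115). Cntn3, a neuronal cell adhesion protein, went from 76.6 ± 0.819 to 0.263 ± 0.0181 CPM (-8.16 ± 0.11, adjusted p = 3.51e-110). Others among the 8 that rose most were Brinp3 (5.57 ± 0.26), the UDP-glucose receptor P2ry14 (4.98 ± 0.12) and the retinaldehyde dehydrogenase Aldh1a1 (4.33 ± 0.25). Mme, the peptidase neprilysin, and Rgs18, a regulator of G protein signalling, had 2 counts each over the wild-type group, for ratios of 74.9 (95% counting interval 20.3 to 624) and 65.8 (17.8 to 549). Among the genes that fell most, Wdr49, the lysophospholipase-like gene Lyplal1, the tetraspanin gene Tspan15 and the complement C5 gene Hc had 0 counts in the KO group and were at least 140-fold, 66.6-fold, 42.4-fold and 26.8-fold lower.

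In the KO line 19 of 20 cholesterol synthesis genes rose and 0 fell (19 and 0 when adjusted over the list alone), among them Fdps (1.58 ± 0.040), Mvd (0.99 ± 0.088) and Hmgcs1 (0.97 ± 0.032), with camera adjusted p = 1.13e-06. Of 30 mitosis genes 26 rose and 3 fell (26 and 3 adjusted over the list alone), including the kinesin Kif20a (1.09 ± 0.030) and cyclin B2, Ccnb2 (1.01 ± 0.033; list adjusted p = 1.13e-06). Glycolysis genes rose at 15 and fell at 3 of 19 members (15 and 3 adjusted over the list alone), with the lactate carrier Slc16a3 at 1.45 ± 0.027 and Pgam1 at 1.15 ± 0.020. Their list passed with the preset correlation (adjusted p = 4e-05) and not otherwise (adjusted p = 0.138 with an estimated correlation). Mesenchymal and matrix genes went both ways, 19 up and 7 down of 32 (19 and 7 adjusted over the list alone): Postn, which encodes periostin, rose by 2.09 ± 0.23 and Col3a1 by 1.81 ± 0.018, while the gelatinase gene Mmp2 fell by 6.59 ± 0.27. That list had adjusted p = 0.000679, and adjusted p = 0.127 with an estimated correlation. The 8 fibroblast and endothelial markers, which share Col3a1 with it, had 5 members up and 0 down (5 and 0 adjusted over the list alone), including the proteoglycan gene Dcn at 1.33 ± 0.020. The fibroblast marker list had adjusted p = 0.0299, and adjusted p = 0.0779 with an estimated correlation.

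Immediate early and heat shock genes, fixed in advance as a sign of handling, fell at 14 and rose at 0 of 17 members (14 and 1 when adjusted over the list alone; camera adjusted p = 2.7e-06), including the transcription factor genes Fosb (-2.63 ± 0.037), Fos (-2.37 ± 0.040) and Egr1 (-2.10 ± 0.021), which went from 1138 ± 26.8 to 266 ± 3.98 CPM. Interferon-stimulated genes had 27 members down, 10 up and 7 not passed of 44 (28 down and 10 up adjusted over the list alone): the chemokine gene Cxcl10 fell by 1.91 ± 0.026 and Oasl1 by 1.39 ± 0.038, while Ifi27l2a rose by 1.23 ± 0.13 (list adjusted p = 0.00292). The list tests above hold with an estimated correlation except where the other p is given. ATF4 targets, which serve amino acid supply under stress, had 17 down and 5 up of 22 (17 and 5 adjusted over the list alone), with Atf3 at -2.94 ± 0.052 and Aldh1l2 at -1.48 ± 0.032. The ATF4 list had adjusted p = 0.000971, and adjusted p = 0.0779 with an estimated correlation. Ribosome biogenesis genes had 19 down and 2 up of 24 (19 and 3 adjusted over the list alone), with the helicase gene Ddx21 at -1.31 ± 0.023. The ribosome list had adjusted p = 0.000971, and adjusted p = 0.0512 with an estimated correlation. DNA replication genes had 22 down and 7 up of 32 (23 and 7 adjusted over the list alone), the ligase gene Lig1 being at 0.81 ± 0.030. The replication list had adjusted p = 0.00375, and adjusted p = 0.0681 with an estimated correlation. Recombination and Fanconi genes had 19 down and 4 up of 30 (19 and 4 adjusted over the list alone). The recombination list had adjusted p = 0.0216, and adjusted p = 0.055 with an estimated correlation. Of 32 p53 targets 22 fell and 8 rose (22 and 8 adjusted over the list alone), among them the cell cycle inhibitor genes Btg2 (-3.61 ± 0.055) and Cdkn1a (-2.37 ± 0.057), with adjusted p = 0.0425, and adjusted p = 0.119 with an estimated correlation.

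The remaining 18 lists did not pass in this comparison. MHC class I genes split evenly, 9 up and 9 down of 20 (9 and 10 when adjusted over the list alone; adjusted p = 0.69), although the classical heavy chain genes H2-D1 and H2-K1 each fell by 1.1 (SE 0.0195 and 0.0324). Chemokines and cytokines had 11 up and 11 down of 25 (the same adjusted over the list alone; adjusted p = 0.691), with the neutrophil chemokine gene Cxcl1 at -2.25 ± 0.065. Apoptosis regulators had 10 up and 9 down of 20 (10 and 9 adjusted over the list alone), a median of 0.07, a mean of -0.01 and a test pointing down (adjusted p = 0.852). Checkpoint ligands had 5 up and 7 down of 12 (5 and 7 adjusted over the list alone), with a median of -0.12 and a mean of 0.06 (test down, adjusted p = 0.69). Epithelial genes had 1 up and 5 down of 11 (1 and 5 adjusted over the list alone; adjusted p = 0.691), NKG2D ligands and death receptors 2 and 5 of 10 (the same adjusted over the list alone; 0.69), and melanosome antigens 0 and 1 of 2, the lineage factor Mitf at -1.16 ± 0.13 (adjusted p = 0.69). Replication-dependent histones, few of whose transcripts carry a poly(A) tail, had 5 up and 1 down of 11 (4 and 1 adjusted over the list alone; adjusted p = 0.118). Leukocyte markers had 1 up and 2 down of 7 (1 and 2 adjusted over the list alone), with a median of 0.23, a mean of -0.33 and a test pointing down (adjusted p = 0.922).

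With GSK3326595, wild-type MC38 cells lost RNA for interferon-stimulated genes, MHC class I presentation and nucleic acid sensing, and for DNA replication and recombination, while genes of cholesterol synthesis, ribosome biogenesis and mitosis rose slightly. Of 6102 changed genes, 2977 rose and 3125 fell. The interferon regulatory factor gene Irf7 went from 117 ± 0.937 to 52.3 ± 1.54 CPM (SD, n = 3 each), a log2 fold change of -1.16 ± 0.033 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.46e-67). The class I light chain gene B2m went from 1444 ± 14.7 to 828 ± 0.812 CPM (-0.80 ± 0.019, adjusted p = 5.32e-77). Among the 8 genes that rose most, all at low levels, were Ly6g (2.23 ± 0.21), whose reads may be shared with close relatives, the chemokine gene Ccl9 (2.13 ± 0.19), the IL-36 receptor gene Il1rl2 (2.11 ± 0.32), the angiopoietin gene Angpt2 (2.08 ± 0.32), hepatocyte growth factor, Hgf (1.85 ± 0.22), and the leukocyte tetraspanin gene Cd53 (1.83 ± 0.35), which reached 1.04 CPM. The 8 that fell most included the imprinted long noncoding RNA H19 (-2.26 ± 0.25), Abi3bp (-1.73 ± 0.26), the complement regulator gene Cd46 (-1.67 ± 0.31), Zc3h6 (-1.59 ± 0.13), the class II invariant chain gene Cd74 (-1.56 ± 0.33) and Herc6 (-1.49 ± 0.075), a ligase for the ubiquitin-like protein ISG15, which went from 23.1 to 8.22 CPM.

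Interferon-stimulated genes fell at 38 of 44 members, rose at 0 and did not pass at 6 (39 down and 0 up adjusted over the list alone), with a median of -0.38 and camera adjusted p = 9.37e-25. Besides Irf7, the virus tethering factor gene Bst2 fell by 0.80 ± 0.024, the guanylate binding protein gene Gbp3 by 0.80 ± 0.033 and the Z-nucleic acid sensor gene Zbp1 by 0.77 ± 0.043. Of 20 class I presentation genes 15 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 9.25e-08), including H2-D1 (-1.08 ± 0.019) and the immunoproteasome gene Psmb9 (-0.91 ± 0.052). Nucleic acid sensing genes had 9 down and 2 up of 16 (10 and 2 adjusted over the list alone; adjusted p = 0.000705), such as Ifi204 (-0.59 ± 0.050) and the RNA-editing enzyme gene Adar (-0.39 ± 0.028). DNA replication genes had 20 down and 2 up of 32 (20 and 2 adjusted over the list alone; adjusted p = 4.83e-05), with E2f2 at -0.61 ± 0.063, and recombination and Fanconi genes had 14 down and 1 up of 30 (16 and 1 adjusted over the list alone; adjusted p = 0.000652), with Exo1 at -0.47 ± 0.044 and Brca1 at -0.44 ± 0.035. Cholesterol synthesis genes rose at 13 of 20 members and fell at 0 (14 and 0 adjusted over the list alone; adjusted p = 4.83e-05), for instance Msmo1 by 0.38 ± 0.034. Ribosome biogenesis genes rose at 13 of 24 and fell at 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000579), for instance nucleophosmin, Npm1, by 0.30 ± 0.016. Mitosis genes rose at 15 of 30 and fell at 4 (16 and 5 adjusted over the list alone; adjusted p = 0.00172), for instance the centromere histone gene Cenpa by 0.41 ± 0.035. These 8 lists also passed with an estimated correlation. MDM2/MDM4 and p53 genes had 4 down and 0 up of 5 (4 and 0 adjusted over the list alone), Mdm4 at -0.15 ± 0.031 among them. The MDM2/MDM4 list had adjusted p = 0.0356, and adjusted p = 0.0736 with an estimated correlation. The immediate early and heat shock list had 9 down and 5 up of 17 (9 and 5 adjusted over the list alone), with Hsph1 at -0.44 ± 0.023 and the phosphatase gene Dusp1 at 0.56 ± 0.029. The handling list had adjusted p = 0.0379, and adjusted p = 0.0706 with an estimated correlation. Fibroblast and endothelial markers had 5 up and 2 down of 8 (5 and 3 adjusted over the list alone; adjusted p = 0.123), among them cadherin 5, Cdh5 (1.64 ± 0.29), and lumican, Lum (1.45 ± 0.056), and 0 of 7 leukocyte markers changed.

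In KO cells GSK3326595 also lowered interferon-stimulated genes, and here genes of mitosis, DNA replication and cholesterol synthesis rose together. Of 7830 changed genes, 4106 rose and 3724 fell. Krt8, a keratin of simple epithelia, went from 14.4 ± 0.608 to 60.1 ± 1.60 CPM (SD, n = 3 each), a log2 fold change of 2.06 ± 0.051 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.07e-74). Islr, a matrix-cell surface protein also called meflin, went from 220 ± 3.99 to 62.7 ± 4.81 CPM (-1.82 ± 0.032, adjusted p = 3.37e-93). The 8 genes that rose most included the growth factor gene Bmp6 (2.60 ± 0.20), the stromelysin gene Mmp10 (2.26 ± 0.21), lysyl oxidase, Lox (2.24 ± 0.39), the epoxide hydrolase gene Ephx2 (2.23 ± 0.36), the B cell adaptor gene Blnk (2.19 ± 0.31), the checkpoint receptor gene Tigit (2.01 ± 0.11), which went from 2.60 to 10.5 CPM, and Krt8. Among those that fell most were H19 (-3.03 ± 0.44), the cation channel gene Trpm5 (-2.73 ± 0.30), the methyltransferase gene Inmt (-2.55 ± 0.23), the retinol uptake receptor gene Stra6 (-2.28 ± 0.20), the peptidase gene Ece2 (-1.87 ± 0.33), Ypel1 (-1.87 ± 0.23) and Islr.

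All 30 mitosis genes rose with GSK3326595 in KO cells (30 adjusted over the list alone; median 0.26, camera adjusted p = 6.71e-12), among them Plk1 (0.55 ± 0.035) and the Aurora kinase gene Aurka (0.39 ± 0.035). DNA replication genes rose at 25 and fell at 4 of 32 members (25 and 4 adjusted over the list alone; adjusted p = 1.39e-07), with Uhrf1 at 0.55 ± 0.028 and the replication origin gene Mcm10 at 0.54 ± 0.038. Of 20 cholesterol synthesis genes 17 rose and 0 fell (17 and 0 adjusted over the list alone; adjusted p = 3.72e-07). Interferon-stimulated genes fell at 39 and rose at 1 of 44 members (40 and 1 adjusted over the list alone; median -0.39, adjusted p = 1.8e-16), with Ifi27l2a at -1.57 ± 0.13 and Irf7 at -0.83 ± 0.036. These 4 lists also passed with an estimated correlation. Class I presentation genes fell at 13 and rose at 4 of 20 (13 and 4 adjusted over the list alone), with H2-K1 at -0.89 ± 0.034 and B2m at -0.86 ± 0.020. The class I list had adjusted p = 0.000441, and adjusted p = 0.081 with an estimated correlation. Nucleic acid sensing genes fell at 11 and rose at 3 of 16 (11 and 3 adjusted over the list alone), with Ifi203 at -0.62 ± 0.035. The sensing list had adjusted p = 0.00337, and adjusted p = 0.081 with an estimated correlation. Polyadenylated histone genes fell at 5 and rose at 0 of 8 (5 and 0 adjusted over the list alone), with the linker histone gene H1f0 at -0.54 ± 0.019. The polyadenylated histone list had adjusted p = 0.0105, and adjusted p = 0.29 with an estimated correlation. Glycolysis genes rose at 12 and fell at 4 of 19 (12 and 4 adjusted over the list alone), with the glucose transporter gene Slc2a1 at 0.53 ± 0.026. The glycolysis list had adjusted p = 0.0179, and adjusted p = 0.48 with an estimated correlation. The immediate early and heat shock genes did not pass as a list, with 5 up and 5 down of 17 (the same adjusted over the list alone; adjusted p = 0.65), although Fos was at -1.64 ± 0.067, and fibroblast and endothelial markers had 2 up and 4 down of 8 (2 and 4 adjusted over the list alone; adjusted p = 0.134), with Col3a1 at -0.82 ± 0.018.

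The response to GSK3326595 was next set against genotype, as the change in KO minus the change in wild-type cells. This difference passed at 6264 genes, 3264 positive and 3000 negative. DNA replication genes were positive at 25 and negative at 0 of 32 members (26 and 0 adjusted over the list alone; median 0.34, camera adjusted p = 1.59e-12), with E2f2 at 0.97 ± 0.097, the origin licensing gene Cdc6 at 0.75 ± 0.055 and Mcm10 at 0.71 ± 0.052. Mitosis genes were positive at 20 and negative at 2 of 30 (20 and 2 adjusted over the list alone; adjusted p = 0.000192), and recombination and Fanconi genes at 16 and 2 of 30 (16 and 2 adjusted over the list alone; adjusted p = 0.000956), such as Exo1 at 0.82 ± 0.064. Fibroblast and endothelial markers were positive at 0 and negative at 6 of 8 (0 and 7 adjusted over the list alone; median -0.79, adjusted p = 0.000159), with Lum at -0.89 ± 0.088 and Col3a1 at -0.75 ± 0.025. These 4 lists also passed with an estimated correlation. Polyadenylated histone genes were negative at 5 and positive at 0 of 8 (5 and 0 adjusted over the list alone), with the DNA damage histone gene H2ax at -0.62 ± 0.061. The polyadenylated histone list had adjusted p = 0.00368, and adjusted p = 0.198 with an estimated correlation. ATF4 targets were negative at 11 and positive at 3 of 22 (11 and 3 adjusted over the list alone), with Trib3 at -0.55 ± 0.038. The ATF4 list had adjusted p = 0.0203, and adjusted p = 0.218 with an estimated correlation. Cholesterol synthesis genes were positive at 8 and negative at 0 of 20 (9 and 0 adjusted over the list alone). The cholesterol list had adjusted p = 0.0214, and adjusted p = 0.0753 with an estimated correlation. Methionine cycle and salvage genes were negative at 5 and positive at 1 of 15 (5 and 1 adjusted over the list alone), with the S-adenosylmethionine synthetase gene Mat2a at -0.39 ± 0.033 and Mtap at -0.24 ± 0.031. The methionine list had adjusted p = 0.0362, and adjusted p = 0.15 with an estimated correlation. Interferon-stimulated genes were positive at 16 and negative at 9 of 44 (16 and 9 adjusted over the list alone; adjusted p = 0.556), Irf7 being positive at 0.33 ± 0.050.

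Single genes that diverged most between the lines with GSK3326595 included Lox (2.59 ± 0.68), which rose from 0.219 to 1.05 CPM in KO cells and was at 0.251 and 0.203 CPM in wild-type cells; without wild-type DMSO replicate 2 its difference was 1.81 and did not pass. Blnk (1.79 ± 0.39) and the cytoskeletal gene Epb41l3 (1.71 ± 0.25) were also higher. On the negative side stood Ece2 (-2.64 ± 0.50), Trpm5 (-2.33 ± 0.38) and Aldh1a1 (-2.0 ± 0.44). Mme and Rgs18 had 2 counts each over the wild-type DMSO group, and 13 and 15 counts with GSK3326595, against 140 and 123 counts in KO cells under DMSO, and 113 and 112 with the inhibitor.

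In wild-type MC38 cells MRTX1719 had small effects, with 537 genes up and 580 down and 18 of them at least 2-fold. Interferon-stimulated genes rose slightly, while mitosis genes and the immediate early and heat shock genes fell. Cryab, a small heat shock protein, went from 61.3 ± 3.01 (SD, n = 3) to 43.1 ± 1.46 CPM (n = 2), a log2 fold change of -0.51 ± 0.046 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.55e-17). Selenoo, a mitochondrial selenoprotein, went from 17.1 ± 1.32 to 25.0 ± 2.33 CPM (0.54 ± 0.064, adjusted p = 2.2e-11). These 2 kept their calls in every alternative. Zc3h6 (-0.78 ± 0.13) and the early growth response gene Egr3 (-0.49 ± 0.063) lost theirs with DESeq2. Without MRTX1719 replicate 3, calls were lost for Col12a1 (0.58 ± 0.13, then 0.52), H19 (-0.97 ± 0.23, then -0.46), Hgf (0.98 ± 0.27, then 0.64), Ocel1 (-0.57 ± 0.16, then -0.38), Radil (-0.50 ± 0.11, then -0.32) and Eef1akmt4 (0.60 ± 0.19, then 0.39). Leaving out DMSO replicate 3 ended the calls of Hgf (0.86), Eef1akmt4 (0.55) and Klhl30 (0.96 ± 0.26, then 0.70), without DMSO replicate 2 those of Ocel1 (-0.47) and Eef1akmt4 (0.60) were lost, and without MRTX1719 replicate 1 that of Klhl30 (0.78). The other named genes lost their calls without any of 4 or 5 single libraries: Hmga1b (1.2 ± 0.28; 1.1 to 1.28 without a library), which has a near-identical relative, the cytokine gene Il6 (0.86 ± 0.29; 0.71 to 0.95), Slfn4 (0.70 ± 0.23; 0.57 to 0.77), the granzyme gene Gzmm (-0.64 ± 0.21; -0.71 to -0.49) and the muscle glycogen phosphorylase gene Pygm (-0.62 ± 0.19; -0.64 to -0.57).

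Interferon-stimulated genes rose at 17 and fell at 0 of 44 members with MRTX1719 in wild-type cells (23 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 7.57e-14), with Ifit3b at 0.38 ± 0.063, Rsad2, the antiviral protein viperin, at 0.33 ± 0.031 and Ifi44 at 0.27 ± 0.031. Mitosis genes fell at 13 and rose at 0 of 30 (16 and 0 adjusted over the list alone; median -0.08, adjusted p = 4.39e-11), such as Nusap1 at -0.21 ± 0.043 and the kinesin gene Kif23 at -0.19 ± 0.032. Immediate early and heat shock genes fell at 11 and rose at 0 of 17 (12 and 0 adjusted over the list alone; adjusted p = 2.69e-11), with Dnajb1 at -0.35 ± 0.031 and Egr1 at -0.34 ± 0.022. These 3 lists also passed with an estimated correlation, and the last, a sign of handling, moved together with the other lists given here. Glycolysis genes fell at 6 and rose at 0 of 19 (9 and 0 adjusted over the list alone), with Slc2a1 at -0.20 ± 0.032. The glycolysis list had adjusted p = 9.74e-06, and adjusted p = 0.142 with an estimated correlation. Class I genes fell at 5 and rose at 0 of 20 (7 and 1 adjusted over the list alone), with H2-D1 at -0.29 ± 0.021 and B2m at -0.25 ± 0.021. The class I list had adjusted p = 0.000392, and adjusted p = 0.0691 with an estimated correlation. Nucleic acid sensing genes rose at 5 and fell at 0 of 16 (5 and 0 adjusted over the list alone), with Ifi204 at 0.29 ± 0.050. The sensing list had adjusted p = 0.000682, and adjusted p = 0.0655 with an estimated correlation. DNA replication genes fell at 3 and rose at 0 of 32 (7 and 0 adjusted over the list alone), Rrm1 at -0.14 ± 0.027 and Pcna at -0.11 ± 0.025 among them. The replication list had adjusted p = 0.00351, and adjusted p = 0.0691 with an estimated correlation. Ribosome biogenesis genes rose at 4 and fell at 0 of 24 (6 and 0 adjusted over the list alone). The ribosome list had adjusted p = 0.0079, and adjusted p = 0.0944 with an estimated correlation. Of 32 p53 targets 4 fell and 2 rose (9 and 2 adjusted over the list alone), with Btg2 at -0.34 ± 0.040. The p53 target list had adjusted p = 0.0493, and adjusted p = 0.137 with an estimated correlation.

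In KO cells MRTX1719 changed 10464 genes, 5486 up and 4978 down, with 1779 at least 2-fold. Genes of mitosis, DNA replication, cholesterol synthesis and the unfolded protein response rose, and interferon-stimulated genes fell. Islr went from 220 ± 3.99 to 17.9 ± 0.740 CPM (SD, n = 3 each), a log2 fold change of -3.62 ± 0.040 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.88e-119), and Bmp6 went from 0.649 ± 0.121 to 18.1 ± 1.53 CPM (4.78 ± 0.15, adjusted p = 2.42e-63). Mmp3, a stromelysin like Mmp10, rose by 4.93 ± 0.47, Blnk by 4.20 ± 0.24, the stress cytokine gene Gdf15 by 3.29 ± 0.41, Lox by 3.29 ± 0.34, Mmp10 by 3.29 ± 0.18 and Usp17la, a deubiquitinase with near-identical copies, by 3.19 ± 0.17. The IL-18 receptor gene Il18r1 had 3 counts over the DMSO group and 95 with MRTX1719, a ratio of 31 (95% counting interval 10.3 to 153). Trpm5 and H19 had 3 and 2 counts left, for ratios of 49.4 (16.6 to 242) and 38.8 (10.4 to 326). Stra6 fell by 4.77 ± 0.29, the sodium pump subunit gene Atp1b2 by 4.07 ± 0.53 and Ypel1 by 3.39 ± 0.30.

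Mitosis genes rose at 26 and fell at 2 of 30 members with MRTX1719 in KO cells (26 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 3.84e-06), with Plk1 at 0.85 ± 0.035 and Aurka at 0.64 ± 0.035. DNA replication genes rose at 25 and fell at 5 of 32 (25 and 5 adjusted over the list alone; adjusted p = 6.07e-05), Mcm10 being at 0.98 ± 0.037 and E2f1 at -0.73 ± 0.059. Of 20 cholesterol synthesis genes 18 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 9.61e-05), with Fdps at 0.75 ± 0.033. Unfolded protein response genes rose at 14 and fell at 2 of 16 (14 and 2 adjusted over the list alone; adjusted p = 0.000507), with the chaperone genes Creld2 at 0.78 ± 0.036 and Dnajb11 at 0.66 ± 0.032, while the transcription factor gene Xbp1 was at -0.71 ± 0.026. Interferon-stimulated genes fell at 30 and rose at 6 of 44 (30 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.000709), with Oasl2 at -0.88 ± 0.030. These 5 lists also passed with an estimated correlation. Class I genes fell at 15 and rose at 4 of 20 (15 and 4 adjusted over the list alone), with Psmb9 at -1.39 ± 0.072. The class I list had adjusted p = 0.0175, and adjusted p = 0.196 with an estimated correlation. Polyadenylated histone genes fell at 6 and rose at 1 of 8 (6 and 1 adjusted over the list alone), H1f0 by 1.29 ± 0.020. The polyadenylated histone list had adjusted p = 0.0199, and adjusted p = 0.274 with an estimated correlation. Fibroblast and endothelial markers fell at 5 and rose at 1 of 8 (5 and 1 adjusted over the list alone), with Col3a1 at -1.35 ± 0.018 and Cdh5 at 1.93 ± 0.29. The fibroblast marker list had adjusted p = 0.0193, and adjusted p = 0.0674 with an estimated correlation. Ribosome biogenesis genes rose at 13 and fell at 4 of 24 (13 and 4 adjusted over the list alone), with Utp20 at 0.86 ± 0.031. The ribosome list had adjusted p = 0.0498, and adjusted p = 0.196 with an estimated correlation. The immediate early and heat shock list went both ways, 9 up and 7 down of 17 (9 and 7 adjusted over the list alone), with Fosb at -2.54 ± 0.072 and a median of 0.14 against a mean of -0.21 (test up, adjusted p = 0.934). Of 32 p53 targets 15 rose and 12 fell (15 and 12 adjusted over the list alone; adjusted p = 0.881), Cdkn1a at 1.59 ± 0.063 among them, and Mdm4, a negative regulator of p53, fell by 1.11 ± 0.035.

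The change with MRTX1719 in KO minus that in wild-type cells passed at 8627 genes, 4494 positive and 4133 negative. Mitosis genes were positive at 27 and negative at 0 of 30 members (27 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 3.44e-09), Plk1 at 1.08 ± 0.066 and Cdca8 at 0.94 ± 0.055 among them. Interferon-stimulated genes were negative at 31 and positive at 1 of 44 (32 and 1 adjusted over the list alone; median -0.34, adjusted p = 2.32e-07), with Mx2 at -1.08 ± 0.13 and Irf7 at -0.86 ± 0.049. DNA replication genes were positive at 24 and negative at 2 of 32 (24 and 2 adjusted over the list alone; adjusted p = 1.8e-06), with Mcm10 at 1.1 ± 0.054. Cholesterol synthesis genes were positive at 17 and negative at 0 of 20 (18 and 0 adjusted over the list alone; adjusted p = 2.85e-05), unfolded protein response genes at 14 and 2 of 16 (14 and 2 adjusted over the list alone; adjusted p = 0.000214), and fibroblast and endothelial markers were negative at 6 and positive at 1 of 8 (6 and 1 adjusted over the list alone; adjusted p = 0.00534). These 6 lists also passed with an estimated correlation. Nucleic acid sensing genes were negative at 10 and positive at 2 of 16 (10 and 2 adjusted over the list alone), with Ifi203 at -0.87 ± 0.052. The sensing list had adjusted p = 0.0189, and adjusted p = 0.142 with an estimated correlation. Polyadenylated histones were negative at 6 and positive at 2 of 8 (6 and 2 adjusted over the list alone), H1f0 at -1.28 ± 0.029 among them. The polyadenylated histone list had adjusted p = 0.0206, and adjusted p = 0.305 with an estimated correlation. Class I genes were negative at 11 and positive at 3 of 20 (11 and 3 adjusted over the list alone), with B2m at -0.79 ± 0.029. The class I list had adjusted p = 0.0406, and adjusted p = 0.302 with an estimated correlation. Among the genes that diverged most in the positive direction were Blnk (3.93 ± 0.36), Bmp6 (3.83 ± 0.58), Gdf15 (3.72 ± 0.54) and Mmp3 (4.80 ± 1.3), which was at 3.24 and did not pass without wild-type DMSO replicate 3. In the negative direction they included Stra6 (-4.44 ± 0.41), Atp1b2 (-3.58 ± 0.79), Islr (-3.40 ± 0.063), Ypel1 (-3.11 ± 0.44) and Ece2 (-2.90 ± 0.55).

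**Figure D3:**
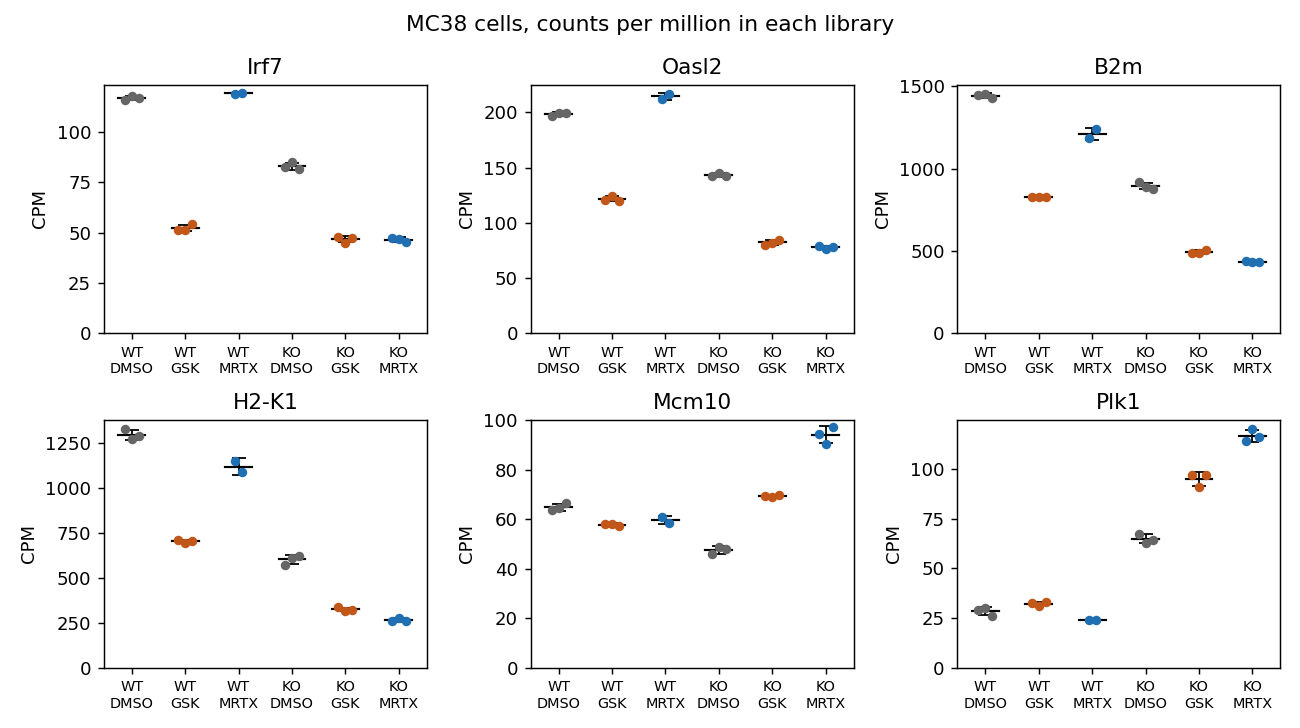
Level in CPM of 6 genes in each MC38 library (points) with the group mean (line) and SD, in wild-type and KO cells with DMSO, GSK3326595 or MRTX1719. Irf7 fell from 117 to 52.3 CPM with GSK3326595 in wild-type cells and was at 119.5 CPM with MRTX1719, while in KO cells it was at 83.0, 46.8 and 46.6 CPM; Mcm10 and Plk1 rose with both inhibitors in KO cells.

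The inhibitors were also compared directly at the same dose and time. In wild-type cells 2283 genes were higher and 2171 lower with MRTX1719 than with GSK3326595. Of 44 interferon-stimulated genes 40 were higher and 0 lower (43 and 0 adjusted over the list alone; median 0.50, camera adjusted p = 7.45e-43), with Irf7 (1.19 ± 0.036) and Ifi44 (1.0 ± 0.032). Class I genes were higher at 14 and lower at 2 of 20 (14 and 2 adjusted over the list alone; adjusted p = 4.3e-08), with H2-D1 at 0.79 ± 0.021. Nucleic acid sensing genes were higher at 11 and lower at 0 of 16 (11 and 2 adjusted over the list alone; adjusted p = 1.92e-06), recombination genes at 11 and 0 of 30 (11 and 0 adjusted over the list alone; adjusted p = 0.000572) and DNA replication genes at 13 and 0 of 32 (13 and 0 adjusted over the list alone; adjusted p = 0.00138). Mitosis genes were lower at 24 and higher at 1 of 30 (24 and 2 adjusted over the list alone; adjusted p = 1.32e-11) and cholesterol synthesis genes at 12 and 0 of 20 (12 and 0 adjusted over the list alone; adjusted p = 4.69e-07). These 7 lists also passed with an estimated correlation, and 5 others passed with the preset correlation alone. Among single genes Abi3bp (1.76 ± 0.28), Cd46 (1.63 ± 0.33) and Herc6 (1.44 ± 0.081) were higher with MRTX1719, and Ly6g (-1.76 ± 0.22), Chrna1 (-1.72 ± 0.32), the collagenase gene Mmp13 (-1.68 ± 0.34) and the complement inhibitor gene Serping1 (-1.67 ± 0.30) lower. Prmt5 did not differ detectably (-0.01 ± 0.031).

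In KO cells 4201 genes were higher and 3688 lower with MRTX1719 than with GSK3326595. Unfolded protein response genes were higher at 15 and lower at 1 of 16 (15 and 1 adjusted over the list alone; adjusted p = 2.12e-06), with the chaperone gene Hspa5 at 0.50 ± 0.016. Interferon-stimulated genes were higher at 28 and lower at 3 of 44 (28 and 3 adjusted over the list alone; adjusted p = 8.02e-05), such as Ifit2 at 0.61 ± 0.029, while Irf7 was at 0.00 ± 0.040. Both lists also passed with an estimated correlation. Glycolysis genes were lower at 15 and higher at 1 of 19 (15 and 1 adjusted over the list alone), with the kinase gene Pdk1 at -0.95 ± 0.026. The glycolysis list had adjusted p = 2.28e-08, and adjusted p = 0.101 with an estimated correlation. ATF4 targets were higher at 17 and lower at 4 of 22 (17 and 4 adjusted over the list alone), with Atf3 at 0.81 ± 0.065. The ATF4 list had adjusted p = 0.0012, and adjusted p = 0.105 with an estimated correlation. Bmp6 (2.18 ± 0.10), Blnk (2.01 ± 0.17) and Gdf15 (2.72 ± 0.36) were higher and Islr (-1.80 ± 0.047) and the synaptic vesicle gene Unc13a (-1.80 ± 0.069) lower.

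Changes with the 2 inhibitors overlapped in each line. In KO cells 3620 genes rose and 3313 fell with both, where independent lists of these sizes would share 1518.4 and 1249.6, and 174 went opposite ways. In wild-type cells 374 rose and 422 fell with both (107.8 and 122.2 for independent lists), and 85 went opposite ways. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.833 (rho = 0.827) in KO and r = 0.493 (rho = 0.467) in wild-type cells. Both comparisons use the same DMSO libraries. Unchanged groups simulated 20 times with a shared control gave r = 0.517 and 0.454, with 0 genes shared. The covariance was 0.279 against a simulated 0.0306 in KO cells, and 0.0604 against 0.0294 in wild-type cells. The 3 DMSO libraries were not split between the comparisons, so part of the excess may come from them.

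In pmel-1 T cells GSK3326595 lowered genes of the interferon response, ATF4 targets and cholesterol synthesis, and raised genes of T cell trafficking and mitosis. Of 7260 changed genes, 3663 rose and 3597 fell. Mx2, an antiviral GTPase, went from 29.7 ± 2.93 to 2.41 ± 0.321 CPM (SD, n = 3 each), a log2 fold change of -3.61 ± 0.12 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.23e-44). Tcf7, the transcription factor TCF1 of naive and memory T cells, went from 28.03 ± 1.1 to 112 ± 2.92 CPM (2.0 ± 0.055, adjusted p = 1.54e-51). Genes that rose most included the chemokine gene Xcl1 (2.94 ± 0.25), the IL-7 receptor gene Il7r (2.89 ± 0.34), the amino acid transporter gene Slc6a19 (2.77 ± 0.28), Nsg2 (2.40 ± 0.16) and Cd7 (2.15 ± 0.16). Those that fell most included, besides Mx2, the transcription factor gene Myrf (-3.49 ± 0.35), the respiratory chain subunit gene Cox6a2 (-3.33 ± 0.21), the antiviral gene Oasl1 (-2.94 ± 0.13), the interferon-inducible GTPase gene Gvin2 (-2.86 ± 0.37), whose reads may be shared with close copies, Fosb (-2.81 ± 0.14) and the ATP-gated channel gene P2rx3 (-2.75 ± 0.23).

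In these T cells interferon-stimulated genes fell at 34 and rose at 8 of 44 members (34 and 8 adjusted over the list alone; median -0.73, camera adjusted p = 1.49e-08), among them Isg15 (-2.31 ± 0.068) and Ifit1 (-2.16 ± 0.085). ATF4 targets fell at 19 and rose at 0 of 23 (19 and 0 adjusted over the list alone; median -1.05, adjusted p = 4.01e-09), with the folate enzyme gene Aldh1l2 at -2.74 ± 0.35 and Nupr1 at -1.82 ± 0.073. Of 21 cholesterol synthesis genes 20 fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 4.01e-09), including Insig1 (-1.08 ± 0.052). Immediate early and heat shock genes, the list that can show handling, fell at 13 and rose at 1 of 16 (13 and 1 adjusted over the list alone; adjusted p = 0.000137), with Egr1 at -1.35 ± 0.039. Trafficking genes rose at 15 and fell at 2 of 17 (15 and 2 adjusted over the list alone; adjusted p = 0.000137), among them the lymph node homing gene Ccr7 (1.57 ± 0.091). Mitosis genes rose at 20 and fell at 1 of 30 (20 and 2 adjusted over the list alone; adjusted p = 0.000486), with Birc5 at 0.66 ± 0.046. These 6 lists also passed with an estimated correlation. Memory genes, which share members such as Ccr7 and Il7r with other lists, rose at 15 and fell at 3 of 21 (15 and 3 adjusted over the list alone). The memory list had adjusted p = 0.000137, and adjusted p = 0.103 with an estimated correlation. A further 8 lists passed with the preset correlation and not with the estimated one. Ribosome biogenesis genes fell at 15 and rose at 3 of 24 (the same adjusted over the list alone). The ribosome list had adjusted p = 0.0061, and adjusted p = 0.339 with an estimated correlation. Arginine methyltransferases fell at 6 and rose at 0 of 9 (6 and 0 adjusted over the list alone), Prmt7 by 0.53 ± 0.058. The methyltransferase list had adjusted p = 0.0187, and adjusted p = 0.185 with an estimated correlation. Polyadenylated histones rose at 6 of 7 and fell at 0 (the same adjusted over the list alone). The polyadenylated histone list had adjusted p = 0.0148, and adjusted p = 0.248 with an estimated correlation. Of 32 p53 targets 15 rose and 6 fell (16 and 6 adjusted over the list alone). The p53 target list had adjusted p = 0.0231, and adjusted p = 0.248 with an estimated correlation.

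Nuclear retained RNAs, a sign of RNA quality, fell at 3 and rose at 0 of 4 (3 and 0 adjusted over the list alone), with the long noncoding RNA Neat1 at -1.39 ± 0.039. The retained RNA list had adjusted p = 0.0436, and adjusted p = 0.223 with an estimated correlation. DNA replication genes had 17 up and 5 down of 32 (18 and 5 adjusted over the list alone). The replication list had adjusted p = 0.0456, and adjusted p = 0.151 with an estimated correlation. Glycolysis genes had 5 up and 11 down of 19 (5 and 12 adjusted over the list alone). The glycolysis list had adjusted p = 0.0456, and adjusted p = 0.166 with an estimated correlation. Class I genes had 11 up and 2 down of 20 (11 and 2 adjusted over the list alone). The class I list had adjusted p = 0.0456, and adjusted p = 0.185 with an estimated correlation. Effector genes went both ways, 10 up and 10 down of 27 (the same adjusted over the list alone; adjusted p = 0.891), with the granzyme gene Gzmf at -1.19 ± 0.11 and Tnf at -0.88 ± 0.045. Exhaustion genes had 7 up and 6 down of 17 (7 and 7 adjusted over the list alone; adjusted p = 0.751), with Havcr2, the receptor TIM-3, at -0.75 ± 0.072, and T cell receptor signalling genes 11 up and 11 down of 29 (14 and 12 adjusted over the list alone; adjusted p = 0.848), with the kinase gene Lck at 1.06 ± 0.033. Markers of other cells did not pass as lists: B cells had 1 up of 5 (adjusted p = 0.583), CD4 T cells 1 up and 1 down of 5 (0.848), myeloid cells 1 up and 1 down of 5 (0.561) and NK cells 2 up of 3 (0.13), each with the same counts adjusted over the list alone. Cd8a, the co-receptor of these cells, went from 558 ± 13 to 841 ± 18.5 CPM (0.59 ± 0.033).

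MRTX1719 in T cells likewise lowered interferon-stimulated genes, with smaller changes elsewhere. Of 5140 changed genes, 2596 rose and 2544 fell. Mx2 went from 29.7 ± 2.93 to 7.0 ± 0.292 CPM (SD, n = 3 each; -2.08 ± 0.10, adjusted p = 7.49e-32 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and Tcf7 from 28.03 ± 1.1 to 45.03 ± 3.40 CPM (0.69 ± 0.061, adjusted p = 5.83e-17). Among the genes that rose most, all at low levels, were Epcam, an epithelial adhesion gene (1.77 ± 0.35), Slc6a19 (1.40 ± 0.33), Ccdc30 (1.35 ± 0.35), and the skeletal muscle genes Myh4 (3.54 ± 0.97) and Acta1 (1.65 ± 0.46). Calls were lost for Ccdc30 (0.97) and Acta1 (1.22) without MRTX1719 replicate 2, for Myh4 (3.65) without DMSO replicate 2, and with DESeq2 for Acta1, Slfn4 and Mir3064. Genes that fell most included, besides Mx2, Gvin2 (-2.48 ± 0.36), Slfn4 (-2.22 ± 0.51), Oasl1 (-1.77 ± 0.12), the long noncoding RNA Tug1 (-1.78 ± 0.35), and the small RNAs Snora28 (-1.91 ± 0.35) and Mir3064 (-1.89 ± 0.44), whose reads may come from host transcripts.

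Of 44 interferon-stimulated genes 39 fell and 2 rose with MRTX1719 (40 and 2 adjusted over the list alone; median -0.70, camera adjusted p = 1.84e-21), with Oas2 at -1.59 ± 0.10 and Isg15 at -1.51 ± 0.063. This list alone passed with an estimated correlation as well. PRMT5 complex and Sm protein genes rose at 11 and fell at 0 of 18 (11 and 0 adjusted over the list alone), with Lsm4 at 0.48 ± 0.040 and Snrpe at 0.45 ± 0.045. The Sm protein list had adjusted p = 0.000242, and adjusted p = 0.0739 with an estimated correlation. Mitosis genes rose at 18 and fell at 0 of 30 (19 and 0 adjusted over the list alone), with Birc5 at 0.56 ± 0.047. The mitosis list had adjusted p = 0.000881, and adjusted p = 0.0737 with an estimated correlation. Nucleic acid sensing genes fell at 8 and rose at 0 of 14 (8 and 0 adjusted over the list alone), with Dhx58 at -0.96 ± 0.067. The sensing list had adjusted p = 0.000881, and adjusted p = 0.227 with an estimated correlation. Polyadenylated histones rose at 5 and fell at 0 of 7 (5 and 0 adjusted over the list alone), with H2az2 at 0.69 ± 0.064. The polyadenylated histone list had adjusted p = 0.00438, and adjusted p = 0.238 with an estimated correlation. DNA replication genes rose at 13 and fell at 2 of 32 (14 and 2 adjusted over the list alone). The replication list had adjusted p = 0.0052, and adjusted p = 0.0739 with an estimated correlation. Memory genes had 8 up and 4 down of 21 (8 and 4 adjusted over the list alone; adjusted p = 0.297), and ATF4 targets 3 up and 11 down of 23 (4 and 11 adjusted over the list alone; adjusted p = 0.106). The handling list of immediate early and heat shock genes had 4 up and 9 down of 16 (4 and 10 adjusted over the list alone; adjusted p = 0.131). The cytotoxic granule gene Gzmb went from 1338 ± 17.1 to 1547 ± 50.2 CPM (0.21 ± 0.031).

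Set directly against each other in T cells, 2660 genes were higher and 2716 lower with MRTX1719 than with GSK3326595. ATF4 targets were higher at 21 and lower at 1 of 23 (21 and 2 adjusted over the list alone; camera adjusted p = 8.23e-14), with Nupr1 at 1.57 ± 0.074, and all 21 cholesterol synthesis genes were higher (21 adjusted over the list alone; adjusted p = 4.01e-13), with Fdps at 0.95 ± 0.036. Glycolysis genes were higher at 15 and lower at 3 of 19 (15 and 3 adjusted over the list alone; adjusted p = 7.59e-06) and immediate early and heat shock genes at 11 and 1 of 16 (11 and 1 adjusted over the list alone; adjusted p = 0.000165), while trafficking genes were lower at 12 and higher at 1 of 17 (12 and 1 adjusted over the list alone; adjusted p = 8.32e-05). These 5 lists also passed with an estimated correlation. Memory genes were lower at 15 and higher at 2 of 21 (15 and 2 adjusted over the list alone), with Tcf7 at -1.31 ± 0.051. The memory list had adjusted p = 2.25e-06, and adjusted p = 0.0526 with an estimated correlation. Gamma chain cytokine genes were lower at 12 and higher at 6 of 21 (12 and 6 adjusted over the list alone), with Jak3 at -0.80 ± 0.037. The gamma chain list had adjusted p = 0.028, and adjusted p = 0.243 with an estimated correlation. Polyamine genes were higher at 7 and lower at 1 of 13 (8 and 1 adjusted over the list alone), with the spermidine synthase gene Srm at 0.79 ± 0.043. The polyamine list had adjusted p = 0.0255, and adjusted p = 0.113 with an estimated correlation. A further 6 lists passed with the preset correlation alone. Interferon-stimulated genes had 13 higher and 15 lower of 44 (13 and 15 adjusted over the list alone; adjusted p = 0.915), with Mx2 at 1.53 ± 0.15 and the GTPase gene Gbp2 at -1.25 ± 0.042. The lipid desaturase gene Scd1 (2.31 ± 0.091) and Il10 (2.79 ± 0.41) were higher, and Xcl1 (-2.51 ± 0.24) and Cd7 (-1.59 ± 0.15) lower. With both inhibitors 1866 genes rose and 1816 fell, against 691.4 and 665.4 for independent lists, and 244 went opposite ways. The correlation across genes was r = 0.66 (rho = 0.652), against 0.517 in 20 simulations of unchanged groups with a shared control. The covariance was 0.129 against 0.0201, part of which may come from the shared DMSO libraries.

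**Figure D4:**
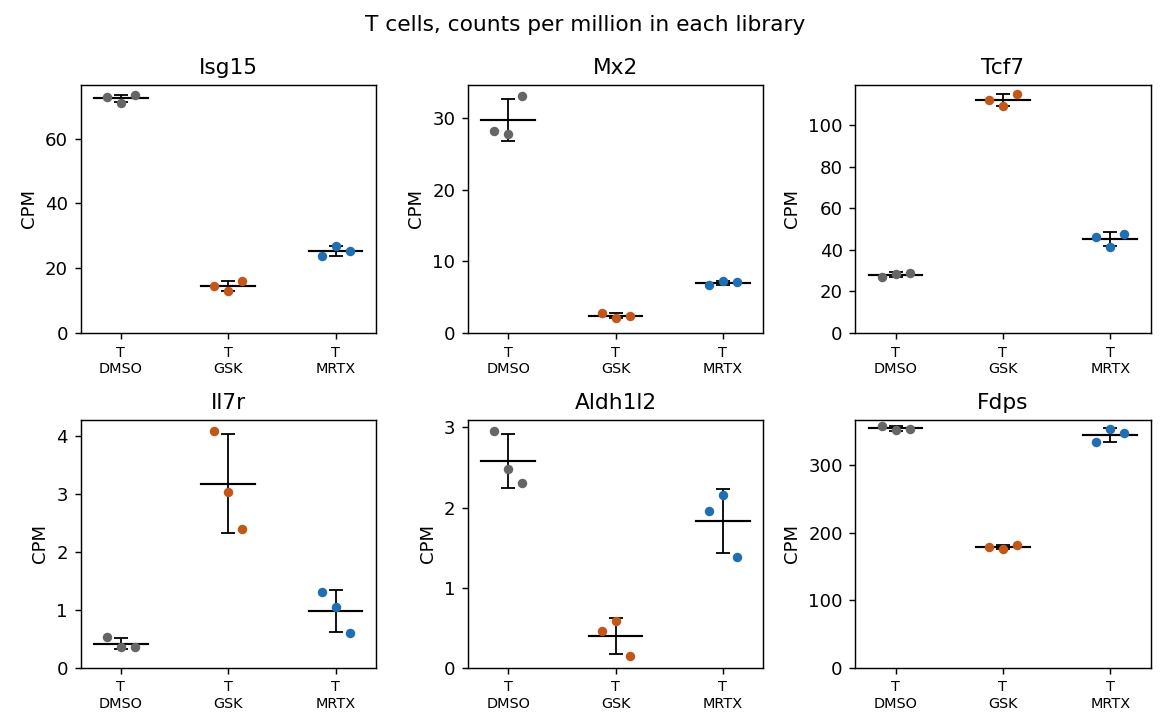
Level in CPM of 6 genes in each T cell library (points) with the group mean (line) and SD. Isg15 and Mx2 were lower with both inhibitors (Isg15 at 72.4, 14.5 and 25.3 CPM with DMSO, GSK3326595 and MRTX1719), and Tcf7 higher, while Fdps was at 355, 179 and 345 CPM and the call of Il7r with MRTX1719 (1.15 ± 0.42) was lost without DMSO replicate 2 or 3 (1.06 each) or MRTX1719 replicate 1 (0.92) or 2 (1.07).

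**Figure D5:**
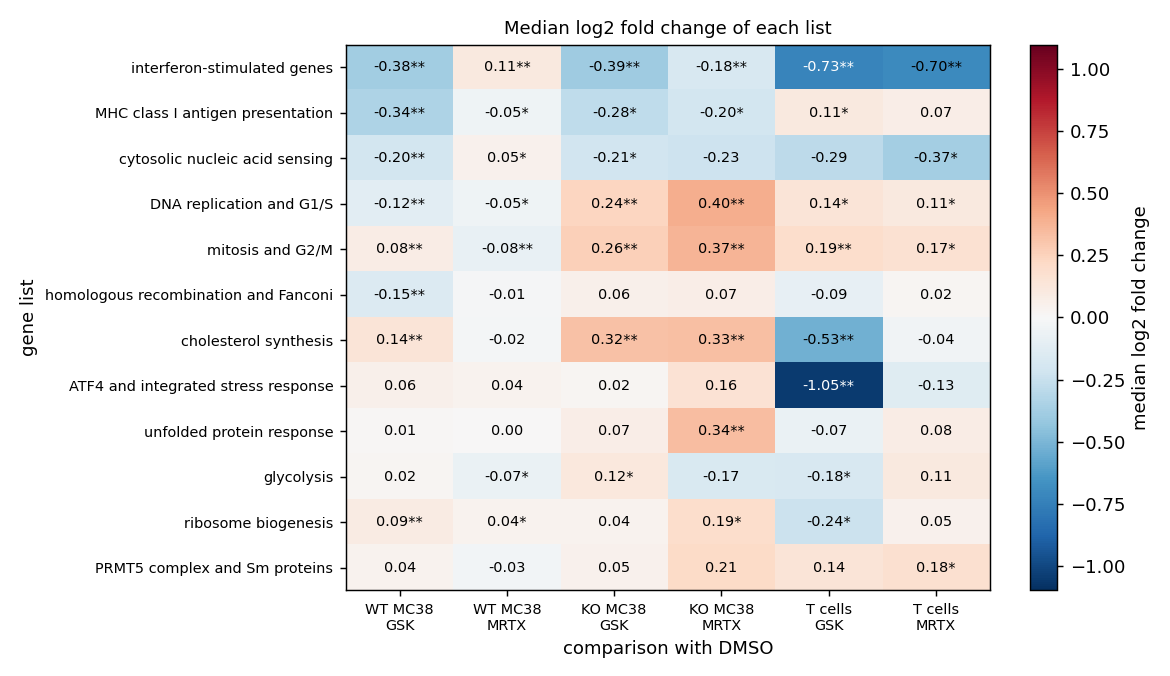
Median log2 fold change of 12 gene lists, picked for the plot after the values were seen, in the 6 comparisons of an inhibitor with DMSO. A star marks a camera adjusted p below 0.05 and a pair of stars a list that also passed with an estimated correlation. Interferon-stimulated genes had medians of -0.38 and 0.11 in wild-type MC38 cells with GSK3326595 and MRTX1719, -0.39 and -0.18 in KO cells, and -0.73 and -0.70 in T cells.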

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

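The tests for mislabelled libraries and for leukocytes were chosen after the results they bear on were seen. The results here are those where the effect of an inhibitor differed between the wild-type and the KO line by a test of that difference.

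For GSK3326595 the effect differed at 6264 genes. The median difference, KO minus wild-type, was 0.34 for DNA replication genes, 0.21 for recombination and Fanconi genes, 0.18 for mitosis and 0.11 for cholesterol synthesis, and -0.79 for fibroblast and endothelial markers, -0.29 for polyadenylated histones, -0.14 for ATF4 targets and -0.08 for methionine genes. Of these, 4 lists did not pass with an estimated correlation, with adjusted p = 0.0753 for cholesterol synthesis, 0.198 for polyadenylated histones, 0.218 for ATF4 targets and 0.15 for methionine genes. Among single genes with positive differences were Lox (2.59), Tmem235 (2.04), Klra6 (1.99), Nacad (1.87), Blnk (1.79), Epb41l3 (1.71), Mir1950 (1.69), which lost its call without any of 7 single libraries (1.14 to 1.77), and Tgm1 (1.61). Negative ones were Rgs18 (-2.88), Mme (-2.85), Ece2 (-2.64), Trpm5 (-2.33), Mtarc1 (-2.09), Aldh1a1 (-2.00), Adam5 (-1.97) and Pcdhb14 (-1.97). The values of Rgs18 and Mme rest on 2 wild-type DMSO counts each. Rgs18 lost its call without wild-type DMSO replicate 2 (-2.32) or GSK3326595 replicate 3 (-2.40) and moved by over 1.5 times without DMSO replicate 3, and Adam5 without wild-type DMSO replicate 3 (-1.63), wild-type GSK3326595 replicate 1 (-1.76) or KO DMSO replicate 1 (-1.67).

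For MRTX1719 the effect differed at 8627 genes. The median difference was 0.45 for DNA replication, 0.40 for mitosis, 0.36 for the unfolded protein response and 0.35 for cholesterol synthesis, and -0.88 for fibroblast and endothelial markers, -0.50 for polyadenylated histones, -0.34 for interferon-stimulated genes, -0.33 for nucleic acid sensing and -0.12 for class I genes. With an estimated correlation polyadenylated histones (adjusted p = 0.305), nucleic acid sensing (adjusted p = 0.142) and class I genes (adjusted p = 0.302) did not pass. Among single genes Mmp3 (4.80), Il18r1 (4.76), Blnk (3.93), Bmp6 (3.83), Lox (3.73) and Gdf15 (3.72) differed upward. Trpm5 (-5.41), Stra6 (-4.44), H19 (-4.08), Aire (-3.71), Atp1b2 (-3.58), Islr (-3.40), Ypel1 (-3.11) and Ece2 (-2.90) differed downward. Il18r1, Trpm5, H19 and Aire rest on 2 or 3 counts in a KO group. The retrotransposon-derived gene Rtl9 had 127 counts in KO cells with MRTX1719 and 19 with DMSO, against 0 and 3 in wild-type cells, and its call was lost without wild-type DMSO replicate 2. Wdr49 had 6 counts in KO cells with MRTX1719 and 0 with DMSO, and its call was lost without any of 4 single KO libraries. Mmp3 lost its call without wild-type DMSO replicate 3 (3.24).

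A first pattern is the wide difference between the KO and the wild-type line under DMSO. Mislabelled libraries are argued against, because 0 of 8 wild-type libraries had Mtap at or below the highest KO library (lowest wild-type 387.8 CPM, highest KO 276 CPM). Copy number differences between the lines stay open. Fold changes correlated with those of 10 neighbouring genes at r = 0.208 (rho 0.259). The 4 inhibitor comparisons with DMSO gave at most 0.114 (0.105). The gap passed the preset margin of 0.1 in rho, not r. Neighbours came from the GRCm38 annotation and placed 89.2% of the genes. The loss of Mtap itself stays open and was not tested, since 1 KO line stands against 1 wild-type line.

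Another pattern is the direction of interferon-stimulated genes with MRTX1719, up in wild-type and down in KO cells. A single library as the whole cause is argued against, since the list median in wild-type cells stayed between 0.095 and 0.117 with any library left out. Leukocytes in the treated libraries stay open, since 0 of 7 tested leukocyte markers rose past the threshold but all lay near the floor, at 0.246 to 1.69 CPM. The Mtap genotype is a candidate explanation that the design names, as a hypothesis only, and since 11 of 17 immediate early and heat shock genes fell in the same wild-type comparison, handling stays open as well, untested.

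In T cells the predicted genes Gm28661 and Gm10925 had the most and the next most counts, 1.55% to 2.18% of a library each, while mitochondrially encoded messenger RNAs had no counts to test. Reads of mitochondrial transcripts counted at nuclear copies may explain this: all 651 words of 31 bases in the reference transcript of Gm28661 occur in mt-Co2 and all 648 of Gm10925 in mt-Atp6, so the lower share is 100%. On that reading their log2 changes in T cells, -0.43 ± 0.028 and -0.40 ± 0.034 with GSK3326595 and -0.15 ± 0.028 and -0.18 ± 0.034 with MRTX1719, would be those of mitochondrial RNA. No biological explanation was tested.

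Other splits of the same libraries, fitted on those libraries alone, were counted for each comparison of 3 against 3. With 10 splits, the share cannot fall below 0.05. The real split called 6224 genes for GSK3326595 in wild-type cells, 7514 for GSK3326595 and 10096 for MRTX1719 in KO cells, 10468 for KO against wild-type, 7590 for MRTX1719 against GSK3326595 in KO cells, and 7262, 5180 and 5261 for GSK3326595, MRTX1719 and their difference in T cells, and the highest of the other splits called 0 in each, so 1 of 10 was as large. For the difference of GSK3326595 effects between the lines 1 of 50 splits, the real one, called as many genes (6220, highest other 4740). Its other splits mixed the lines within treatments, so their calls carry the difference between the lines and cannot show this either.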

How the results depend on the processing

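All alternatives were planned. The 12 counts of changed genes stayed within 1.5 times under each of them, with 1 exception: MRTX1719 in wild-type cells, with 2 treated libraries, gave 433 to 912 genes with a library left out (433 without MRTX1719 replicate 1, 510 without replicate 3), fewer samples being the construction of that setting. Libraries with the same replicate number did not deviate together (r from -0.049 to 0.045 in MC38 cells and -0.04 to 0.039 in T cells), and 5 of 17 and 5 of 9 libraries correlated best with their own number, so the numbers were not taken to pair the samples. With the replicate block the counts were 6023, 7779, 1010 and 10415 for GSK3326595 in wild-type and KO cells and MRTX1719 in the same, 10830 for KO against wild-type, and 7195 and 5036 in T cells, and 5 list calls were lost.

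Of 366 list results, 65 lost their call with an estimated correlation, and fry, which does not compare a list with other genes, gave 163 further calls. Among 1487 named gene values, DESeq2 ended 67 calls, no filter 53, limma 30 and the block 6, while leaving out single libraries ended 399 calls over 10096 results. In at least 1 alternative 48 of 93 named genes lost their call with MRTX1719 in wild-type cells and 22 of 123 between inhibitors there.

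Signs turned only for values that had not passed, and the cause was not tested. These were Pmel with GSK3326595 in wild-type cells (0 with the stricter filter and 0 with the groups alone, -0.11 to 0.09 with a library left out) and with MRTX1719 in T cells (-0.24 to 0.07), Prmt5 between inhibitors in wild-type (-0.02 to 0.01) and KO cells (-0.01 with no filter, -0.02 with the groups alone, -0.01 to 0.03 with a library left out), and Mtap with GSK3326595 in T cells (0 with median-of-ratios scaling, DESeq2 and the groups alone, 0.01 with no filter and limma, -0.04 to 0.03 with a library left out). With fry, adjusted p in the other direction was 0.634 for arginine methyltransferases, 1.67e-06 for checkpoint ligands, 0.0263 for NKG2D ligands and 0.451 for p53 targets with GSK3326595 in KO cells. For MRTX1719 in KO cells it was 7.31e-10 for immediate early genes, 5.99e-08 for mesenchymal genes and 0.00241 for NKG2D ligands, which had 0.606 in KO against wild-type. For the difference between the lines it was 0.106 for mesenchymal genes and 0.0763 for p53 targets with GSK3326595, and 0.000385 for epithelial genes, 0.00432 for MDM2/MDM4, 2.6e-05 for mesenchymal genes and 0.00556 for NKG2D ligands with MRTX1719. Between inhibitors in KO cells it was 0.927 for chemokines, 0.0456 for immediate early genes and 0.949 for class I genes, and 0.48 for recombination genes with MRTX1719 in T cells. With the block, replication-dependent histones had 0.99 with MRTX1719 in KO cells and 0.992 in its difference between the lines, and DNA replication 0.994 between inhibitors in T cells.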

Other observations

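Apart from the groups above, KO cells with MRTX1719 changed several single genes of polyamine, methionine and immune lists that did not pass as a whole (camera adjusted p from 0.328 to 0.934). The polyamine acetyltransferase gene Sat1 rose by 1.32 ± 0.030 and Sat2 fell by 1.94 ± 0.21, while Mat2a fell by 0.90 ± 0.024 and Cth rose by 0.71 ± 0.044. The receptor ligand gene Pvr rose by 1.19 ± 0.027 and the galectin gene Lgals3 by 1.02 ± 0.021, and the checkpoint gene Vsir fell by 1.41 ± 0.072. Among cytokine genes Csf2 rose by 2.67 ± 0.36 and Il33 by 1.81 ± 0.21, and Il18 fell by 2.27 ± 0.33.

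A hypothesis fixed before its result was seen was that MRTX1719 gives a weaker form of the KO response in cells that keep Mtap. Across the 1277 genes that changed at least 1.5-fold the same way with both inhibitors in KO cells, rho between the MRTX1719 changes in KO and wild-type cells was 0.158 (99th percentile of 1000 random gene sets 0.137), and in T cells 0.123 (0.117; 760 genes). Both lie between the preset bounds of 0.1 and 0.2, so the hypothesis stays undecided. The GSK3326595 changes gave 0.534 in wild-type (99th percentile 0.338) and 0.263 in T cells (0.195).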
